A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

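The series profiled binding of the oestrogen receptor ERα by ChIP-seq, in which DNA bound by a protein is recovered from crosslinked chromatin with an antibody and sequenced. Primary mouse mammary epithelial cells carried, per the labels, floxed p53 alleles and a label component written WcrH, either alone or with an HA-tagged human or HA-tagged mouse ERα. AdCre, an adenovirus that delivers Cre recombinase, was added and the cells were harvested after 72 h. The HA tag is a short peptide recognised by the HA antibody, and cells without a tagged receptor served as the background control. MCF7, an established oestrogen receptor-positive human breast cancer line grown in full medium, was profiled with an antibody against ERα itself. Per the labels' protocols, chromatin was crosslinked with 2 mM DSG for 35 min and then with 1% formaldehyde for 10 min. The antibody amounts given were 25 ug for HA and 10 ug for ERα. The 8 libraries form 4 groups of 2, assigned from the sample titles. The labels do not say whether the replicates of a group came from separate animals or cultures, so the spread between them may be technical.

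The deposited files are peak lists, 1 per library, with 5 columns and no header: chromosome, start, end, the name of a MACS peak and a score. Per the submitters' processing notes, the tools were BWA, a read aligner, and MACS 1.4, a peak caller, and the builds were mm9 and hg19, given without roles. The mouse lists were read as mm9 and the MCF7 lists as hg19, after their organism. The score in the deposited lists is the authors' value for each peak. No list has a score under 70. In MCF7, 47 and 92 peaks had scores of 3100 or above, most of them tied at 3100, so the order of the strongest peaks is not resolved. MACS 1.4 usually writes a transformed p-value in this column, but neither a header nor a label says so here. In the HA-ERα and MCF7 lists some peak names occur on more than 1 line, and in the control lists, the MCF7 lists and human ERα replicate 2 some numbers are skipped, as splitting or filtering of peaks before deposit would leave. What was done, which control the peaks were called against, and the read depth are not given in the sources used here. If lists were called against the same control library, part of their overlap may come from it. Scores were used to rank or select peaks within a list. Where printed, they are as deposited and are not comparable between lists.

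Positions are printed 1-based. No mm9 or hg19 sequence or annotation was used. The gene table at hand describes GRCm38, and 266 peaks of the HA-ERα lists, on 6 chromosomes, lay past the last gene of that build, so peaks were not matched to it. Regions are therefore given by position, and the planned results on start sites, oestrogen response elements, gene lists and genes shared with MCF7 were not made. Esr1, Greb1, Pgr and Tff1, which were to be given in every group, could not be placed for the same reason.

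Peaks were counted as shared at an overlap of at least 1 bp, and the Jaccard index is the number of bases covered by both lists over the number covered by either. For comparisons among the 4 HA-ERα lists, peaks overlapping a peak of either control library were first removed. The chance level of an overlap came from 1000 shifts of 1 list, each chromosome moved by a random distance and wrapped at the highest peak end. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and take peaks as independent. Regions are overlapping peaks joined over the lists compared. Numbers of peaks were compared by exact permutation tests, two-sided. With 2 lists against 2 no p-value under 0.333 is possible, and with 4 against 2 none under 0.0667. Chromosome lengths were taken as the highest peak end over the lists of the species. Control blocks are stretches with 3 or more control peaks, both lists pooled, and gaps under 100 kb.

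Groups, the comparisons of peak numbers, overlaps and receptor-specific regions, the shares per chromosome and most alternatives were fixed before the data were examined. Named regions followed a rule fixed at the same time: per ERα group, the 8 regions with the highest mean rank by score among those in both replicates and in no control list; up to 8 regions in both control lists; and the 5 highest regions in both lists of 1 receptor and neither of the other. The alternatives were an overlap of 50% of the shorter peak, a reciprocal overlap of 50% of each peak, peaks extended by 500 bp, peaks above the median score of their list, lists of the same length, control peaks kept, autosomes and X only, the X left out, a replicate block, in which only lists with the same replicate number were compared, and each library left out. Added after seeing the data were lists of the top 2000 peaks, removal of peaks within 100 kb of a control peak, and numbers of peaks outside the control blocks. Also chosen after seeing the data were the control blocks, the score classes, the clusters of regions, Fisher's exact tests of chromosomes between the MCF7 replicates, and the tests of list length on the replicate-number pattern and of base composition. A permutation test over bins of chromosome 13 took the place of the Fisher test first written. The overlap code was tested on simulated data and recovered 9 of 9 known quantities. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.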

Results

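Peak lists from 8 ChIP-seq libraries were compared. They came from mouse mammary epithelial cells without a tagged receptor (control, n = 2), with HA-tagged human ERα (n = 2) or with HA-tagged mouse ERα (n = 2), all precipitated with the HA antibody, and from MCF7 cells precipitated with an ERα antibody (n = 2). The read depth behind the lists is unknown. The control lists held 168 and 158 peaks. The human ERα lists held 8010 and 13250 peaks, the mouse ERα lists 6844 and 7910, and the MCF7 lists 7264 and 7490. Median peak width was 224 and 226 bp in the control lists, 650 and 550 bp with human ERα, 600 and 500 bp with mouse ERα, and 400 and 500 bp in MCF7.

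The first comparison asks how much of the HA signal depended on a tagged receptor. Cells with HA-ERα gave 9004 ± 2880 peaks per library (SD, n = 4), against 163 ± 7.07 in control cells (SD, n = 2), a ratio of 55.2. The ratio was 65.2 for human ERα (10630 ± 3705, SD, n = 2) and 45.3 for mouse ERα (7377 ± 754, SD, n = 2). Every HA-ERα list was longer than both control lists. The difference gave p = 0.0667 in an exact two-sided permutation test of 4 lists against 2, the smallest p this design allows.

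**Figure D1:**
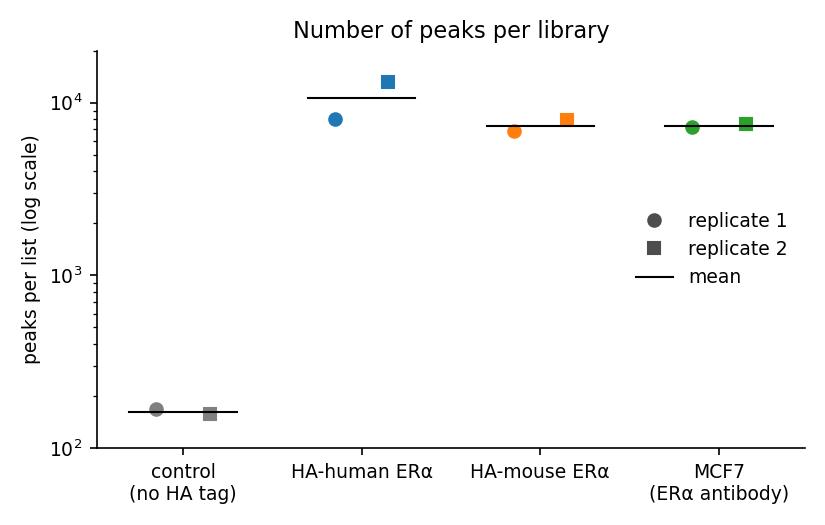
Number of peaks in each list (log scale) by group, with circles for replicate 1, squares for replicate 2 and a line at the mean. The control lists held 168 and 158 peaks, and the 4 HA-ERα lists between 6844 and 13250.

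The control peaks lay in a few dense blocks. Of the control peaks, 86.9% in replicate 1 and 91.8% in replicate 2 fell in 10 blocks. The largest block, on chromosome 8 from 19711562 to 20032884 (mm9), spans 321 kb and held 96 and 95 control peaks. A block on chromosome 5 from 14926094 to 15201966 held 15 in each list. On chromosome 1, blocks from 85247111 to 85279472 and from 87391512 to 87522172 held 9 each in replicate 1, and 9 and 10 in replicate 2. Chromosome 8 thus held 60.2% ± 1.74 (SD, n = 2) of control peaks, 12.1 times its share of the genome's length.

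Most of these blocks also held peaks in cells with a tagged receptor, but the block on chromosome 2 from 181665108 to 181665522 held 0 in all 4 HA-ERα lists. The block on the X from 123303300 to 123305927 held 0 in both human ERα lists and 1 in each mouse ERα list. The chromosome 8 block held 42 and 45 peaks in the human ERα lists and 42 and 45 in the mouse ERα lists. Of the control peaks, 54.8% (replicate 1) and 57.0% (replicate 2) were found in all 4 HA-ERα lists. The control replicates shared 67.3% (95% interval 59.6 to 74.3) and 68.4% (60.5 to 75.5) of their peaks with each other. Most control peaks lay in a few blocks and are not independent, so these intervals may be too narrow. Of the regions in both control lists, chromosome 1 from 87488317 to 87489951 had the highest mean rank, with scores of 344 and 578. Chromosome 17 from 13743861 to 13744179 scored 294 and 334. The other 6 of the 8 named control regions all lay in the chromosome 8 block, the highest of them from 19944624 to 19945143, with scores of 479 and 301.

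In HA-ERα cells these background peaks were a small share. An overlap with a control peak was found for 0.886% (95% interval 0.693 to 1.12) and 0.558% (0.439 to 0.701) of peaks in the human ERα lists. In the mouse ERα lists it was found for 1.02% (0.798 to 1.29) and 0.860% (0.668 to 1.09). The mean over the 4 lists was 0.832% ± 0.196 (SD, n = 4). With a reciprocal overlap of 50% of each peak the mean was 0.246%. The control lists held only 213 regions together, so the share could hardly be large and follows mostly from the peak numbers. Calling against or filtering by the control would also lower it, and whether this was done is not known.

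The second comparison asks whether human and mouse ERα occupied the same sites in mouse cells. Of 14064 regions left after removal of control peaks, 5094 (36.2%) were in all 4 lists, while 4036 were in human ERα replicate 2 alone, the longest list. Mouse ERα peaks were found in the human ERα lists at 87.6% (human replicate 1) and 93.8% (human replicate 2) for mouse replicate 1. For mouse replicate 2, 6195 and 7525 of 7842 peaks were found in the same lists. Human ERα replicate 1 had 74.4% and 77.6% of its peaks in the mouse lists, and the longer human replicate 2 had 48.1% and 56.9%. Shifted lists gave on average 0.355% for human replicate 1 in mouse replicate 1 and at most 0.592% over 1000 shifts.

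The strongest sites coincided between the receptors. Of the 8 top-ranked regions of each receptor, 6 were the same. They included chromosome 17 from 75509527 to 75510825, the highest of both, chromosome 18 from 60765511 to 60768410, chromosome 15 from 101337022 to 101338356, chromosome 13 from 93363603 to 93364733, chromosome 7 from 54363691 to 54365194, and chromosome 17 from 14952626 to 14953808. The chromosome 17 region at 75509527 scored 2145 and 3100 with human ERα and 2039 and 3100 with mouse ERα. The human ERα top 8 further held chromosome 13 from 16085239 to 16086527 and chromosome 17 from 34347117 to 34348353. The mouse ERα top 8 further held chromosome 13 from 71790698 to 71791971 and chromosome 3 from 136102644 to 136103707. These 4 regions were called in all 4 lists as well. With each list divided by score into 5 classes of the same size, in the highest class between 98.5% and 100% of peaks were found in each list of the other receptor. In the lowest class the share ranged from 8.46% (human replicate 2 in mouse replicate 1) to 86.7% (mouse replicate 2 in human replicate 2).

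**Figure D2:**
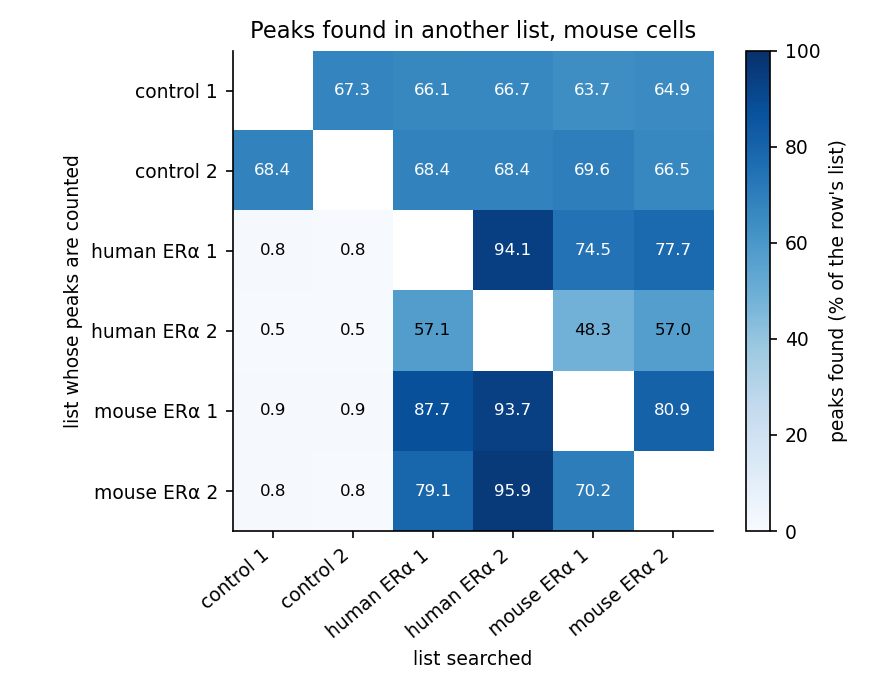
Share of the peaks of each row's list (percent, lists as deposited) that overlap a peak of the column's list by at least 1 bp, for the 6 lists from mouse cells. HA-ERα lists share 48.3 to 95.9% of their peaks with each other, and under 1% with a control list.

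Lists of 1 receptor were not more alike than lists of different receptors by more than the spread between pairs. The Jaccard index was 0.550 ± 0.00538 (SD, n = 2 pairs) between replicates of a receptor and 0.541 ± 0.0651 (SD, n = 4 pairs) between receptors. The 4 pairs share lists, so their SD is not a spread of independent values. Against mouse replicates 1 and 2, human replicate 1 had 0.611 and 0.573, and the longer human replicate 2 had 0.463 and 0.516. Among the 3 ways to pair the 4 lists, the pairing by receptor ranked in the middle (exact permutation p = 0.667, smallest possible 0.333). Lists with the same replicate number but different receptors had the highest index, 0.564 ± 0.0674 (SD, n = 2 pairs). The difference, pairs of different receptors minus pairs of the same receptor, was −0.00936, and its sign turned in 5 alternatives. It was 0.0135 with different receptors compared only between lists of the same number, 0.00368 with lists of the same length, 0.00227 with peaks extended by 500 bp, 0.0171 with the top 2000 peaks, and 0.0383 without human ERα replicate 2.

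Regions specific to human ERα had a lower median rank than regions in all 4 lists. In both human ERα lists and neither mouse ERα list there were 723 regions, and in both mouse ERα lists and neither human list 16. The human-only regions had a median rank at percentile 26.4 of their lists, against 72.3 for regions in all 4 lists by their human ERα ranks. The highest rank was percentile 66.3 for a human-only and 34.7 for a mouse-only region. None of the 723 or the 16 lay above percentile 80 in both lists concerned. Peaks missing from another list scored low without a receptor difference as well. In MCF7, peaks of replicate 1 only and of replicate 2 only had median scores of 100 and 104. Those found in the other replicate had 204 and 259. A low rank therefore cannot be tied to the receptor. The highest human-only regions were chromosome 15 from 85946386 to 85947506, with scores of 139 and 296, and chromosome 2 from 32500501 to 32501200, with 142 and 264. Next came chromosome 6 from 136855150 to 136855349, chromosome 4 from 119928404 to 119928953, and chromosome 16 from 92275683 to 92276338. The highest mouse-only regions were chromosome 10 from 82783667 to 82784124, with scores of 84.5 and 145, and chromosome 7 from 71218198 to 71218997, with 105 and 104. The others named by the rule were chromosome 3 from 140808444 to 140808843 and from 122757194 to 122757343, and chromosome 6 from 74770667 to 74771166.

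These counts depended on list length. With each list cut to its 6774 highest-scoring peaks, the length of the shortest, 186 regions were human-only and 154 mouse-only, and 4491 of 9448 regions (47.5%) were in all 4 lists. Pairing the lists by receptor gave 739 pair-specific regions as deposited and 340 at the same length. Pairing by replicate number gave 1199 and 834, and the crossed pairing gave 288 and 285. They also depended on single libraries, as leaving a library out lets 1 list stand for its receptor. The human-only count was 4772 without human ERα replicate 1, 1016 without human replicate 2, 1350 without mouse replicate 1 and 1710 without mouse replicate 2. The mouse-only count was 32, 319, 268 and 264 in the same order.

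**Figure D3:**
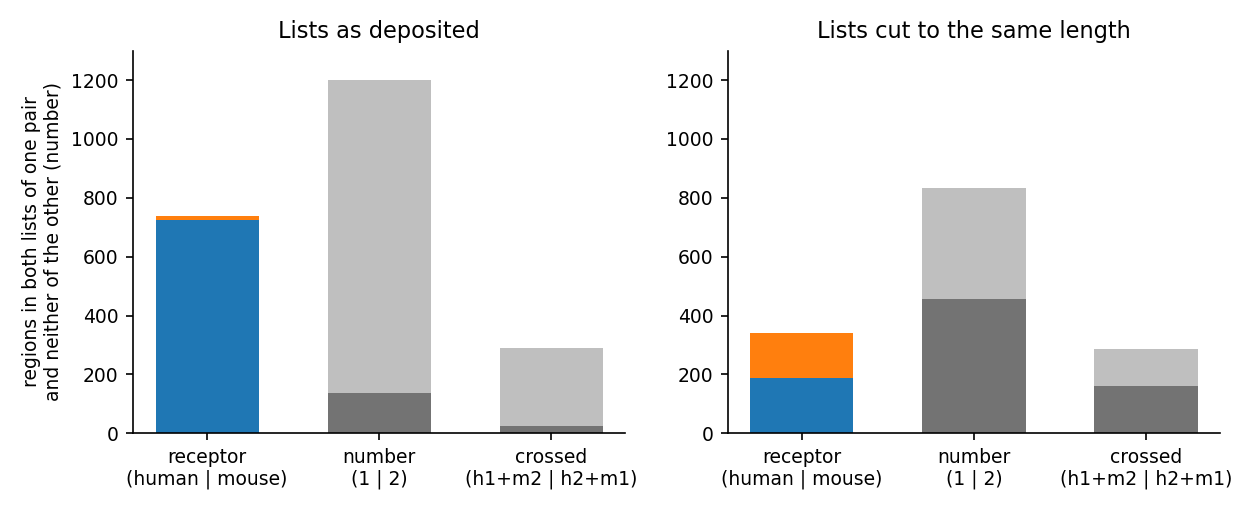
Number of regions called in both lists of a pair and neither list of the other pair, for the pairing by receptor (lower segment human, upper segment mouse), by replicate number (lower segment number 1, upper segment number 2) and crossed (lower segment human 1 with mouse 2, upper segment human 2 with mouse 1). Pairing by receptor gives 739 and 340 regions, fewer than pairing by number, with 1199 and 834.

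Replicates were compared within each group. Human ERα replicate 1 had 94.2% of its peaks in replicate 2, and replicate 2 had 56.9% in replicate 1. For mouse ERα, 80.8% of replicate 1 peaks were in replicate 2, and 5487 of 7842 replicate 2 peaks were in replicate 1. The shares were 73.5% and 70.7% for MCF7. Shifting the lists gave mean shares of 0.661%, 0.378% and 0.264% for the first direction in the 3 groups. With lists of 6774 peaks the human ERα replicates shared 80.8% of their peaks and the mouse ERα replicates 76.5% (means of both directions). In MCF7, 97.2% and 97.9% of peaks in the highest score class were found in the other replicate, and 44.4% and 38.0% in the lowest class.

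In MCF7, 5281 of 9399 regions were called in both replicates. The named regions with the highest ranks were, in hg19, chromosome 11 from 76482910 to 76484376, chromosome 10 from 95194472 to 95195671, chromosome 12 from 89858319 to 89859502, chromosome 5 from 128513115 to 128514188 and chromosome 4 from 28315136 to 28316935. Each scored 3100 or above in both replicates. Chromosome 1 from 186121550 to 186122899 and chromosome 10 from 9228522 to 9231124 and from 104927877 to 104929224 scored 3100 in both, tied with further regions. In all, 47 and 92 MCF7 peaks had scores of 3100 or above. MCF7 and mouse lists lie on different genomes and were not overlapped.

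The distribution over chromosomes was alike in the 4 HA-ERα lists and uneven at the X chromosome. The X held 1.47% ± 0.132 (SD, n = 4) of HA-ERα peaks, 0.233 ± 0.0208 times its share of length, with single lists between 0.213 and 0.262. Chromosomes 9 and 11 held 1.35 ± 0.0354 and 1.33 ± 0.0509 times their share of length (SD, n = 4). In MCF7 the X held 0.546 ± 0.000583 times its share of length (SD, n = 2). In control cells it held 0.532 ± 0.0454 times its share (SD, n = 2), from 6 and 5 peaks. Of these, 6 and 1 lay in the control block from 166424204 to 166443601, and 0 and 3 in that from 123303300 to 123305927. The control ratio thus reflects a few blocks and is no baseline for the HA-ERα lists. No other baseline was used. The X ratios in HA-ERα and MCF7 lists are set against length only, and whether they reflect less binding on the X is open.

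**Figure D4:**
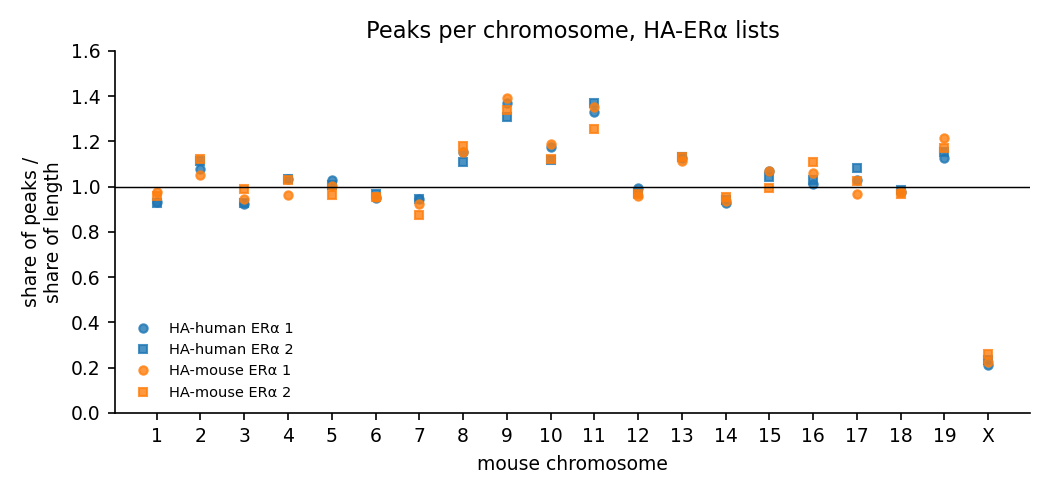
Share of peaks on each mouse chromosome over the chromosome's share of length, for the 4 HA-ERα lists, with circles for replicate 1 and squares for replicate 2. The X lies between 0.213 and 0.262 in all 4 lists, below every autosome.

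The MCF7 replicates differed from each other on chromosomes 13 and 19. Chromosome 13 held 182 peaks in replicate 1 and 270 in replicate 2 (Fisher's exact test over peaks, adjusted p = 0.00122, Benjamini-Hochberg over 23 chromosomes). Chromosome 19 held 300 and 202 (Fisher's exact test, adjusted p = 3.95e-05). On the other chromosomes the ratio of replicate 2 to replicate 1 ran from 0.890 to 1.16, with adjusted p of at least 0.447. Peaks are not replicates, so these tests compare 2 lists and not conditions. On chromosome 13 beyond 30 Mb, 102 peaks were in replicate 2 only and 11 in replicate 1 only, whereas from 20 to 30 Mb the counts were 11 and 14. On chromosome 19 the first 10 Mb held 21 peaks in replicate 1 only and 20 in replicate 2 only, and from 50 to 60 Mb the counts were 35 and 4.

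**Figure D5:**
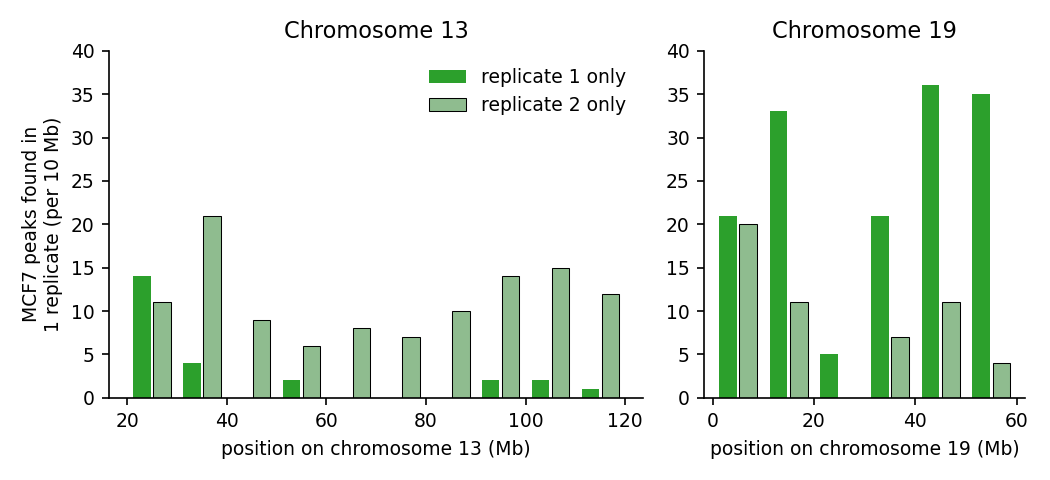
MCF7 peaks found in only 1 of the 2 replicates, per 10 Mb of chromosomes 13 and 19 (hg19). Replicate 2 exceeds replicate 1 in 9 of the 10 bins of chromosome 13, and from 50 to 60 Mb on chromosome 19 the counts are 35 in replicate 1 only and 4 in replicate 2 only.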

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

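Counts of peaks or regions and their ratio were taken to have moved when they differed more than 1.5 times, shares and chromosome ratios when they differed by 1 SD between lists or more, and the difference in Jaccard index only when its sign turned. By these criteria, of 102 alternative values for 12 results, 74 did not move, 23 moved and 5 turned sign. Some of the 74 could not move. A mean share or chromosome ratio shifts by under 1 SD when 1 of the averaged lists is left out. Halving all lists at the median score fixes the ratio of peak numbers. For the share found in both replicates the SD was that between the 2 directions of a pair, which is wide for the human ERα lists, so their values count as unmoved more readily (75.5% as the mean of both directions, 80.6% with both lists cut to 7939 peaks, the length of the shorter). The difference in Jaccard index, −0.00936 as reported, became 0.00227 with peaks extended by 500 bp, 0.00368 at the same list length and 0.0171 with the top 2000 peaks. It ran from −0.0646 (without human ERα replicate 1) to 0.0383 (without human ERα replicate 2), and it was 0.0135 with the replicate block. The number of human-only regions, 723 as reported, was 350 among peaks above the median score, 186 at the same list length and 62 with the top 2000 peaks, and ran from 723 to 4772 when each library was left out. The number of mouse-only regions, 16 as reported, was 40 with a reciprocal overlap of 50%, 9 among peaks above the median score, 154 at the same list length and 40 with the top 2000 peaks, and ran from 16 to 319 when each library was left out. Leaving out a library lets 1 list stand for a receptor, which by construction admits more regions. The ratio of peak numbers, 55.2, was 55.6 with the replicate block and stayed within 46.6 and 59.7 when each library was left out. Outside the control blocks it was 510, a rise fixed by construction and no support for the ratio, because the blocks were drawn from the control peaks and removed 86.9% and 91.8% of them. The share of HA-ERα peaks overlapping a control peak was 0.246% with a reciprocal overlap. The share found in both replicates was 63.2% (control) and 67.3% (MCF7) with a reciprocal overlap, and 71.2% among control peaks above the median score. For the X chromosome the ratio to length was 0.186 in the HA-ERα lists and 0.586 in MCF7 among peaks above the median score. For chromosome 8 in control lists it was 13.4 among peaks above the median score and 11.7 with the X left out. Restriction to autosomes and X moved nothing, because the lists hold no other sequence. The labels do not say that a replicate number marks a shared day, and with 2 pairs per comparison the pairing cannot be established. Alternatives for start sites, response elements and genes were not run, as no annotation of the builds was used. The top 2000 peaks and the ratio outside the control blocks were added after seeing the data. Read depth is unknown, so whether a peak missing from 1 list was weakly bound or under-sampled there is open.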

Other observations

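ERα binding regions lay closer together than randomly placed regions in both species. Among the 5094 regions in all 4 HA-ERα lists, 16.4% had the next region within 20 kb, against at most 5.01% in 1000 random placements within chromosomes. Among the 5281 regions in both MCF7 lists the share was 21.1%, against at most 4.51%. Random placement takes no account of unequal gene content, so these shares describe clumping and not its origin. In mouse cells 6 clusters held 5 or more regions, 35 regions in all. The largest lay on chromosome 9 from 8692997 to 8758945 (mm9) with 8 regions, followed by chromosome 12 from 16759725 to 16803761 and chromosome 6 from 108608236 to 108659935 with 6 each. In MCF7 19 clusters held 107 regions. Those of 7 regions lay on chromosome 10 from 29393572 to 29454271, chromosome 12 from 97885019 to 97963352, chromosome 4 from 102837036 to 102892285 and chromosome 6 from 120271601 to 120299000 (hg19).

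A pair of intervals, chosen after their values were seen, were listed in a control library and ranked high in the HA-ERα lists. On chromosome 8 from 96703197 to 96704437, control replicate 2 held its highest-scoring peak, with a score of 1605, and control replicate 1 listed none. The same interval ranked 16 and 1 in the human ERα lists and 119 and 9 in the mouse ERα lists. Of the 20 highest peaks of human ERα replicate 2 outside the control blocks, it was the only 1 in that control list. On chromosome 2 from 138073806 to 138074134, control replicate 1 had a peak scoring 78.9, which ranked 150 of its 168 peaks. The same interval ranked 90 and 179 in the human ERα lists and 111 and 158 in the mouse ERα lists.

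In the next 3 paragraphs, the tests of list length on the replicate-number pattern and of base composition were chosen only after the result was seen, while the others were written beforehand. Human-only regions outnumbered mouse-only regions by 723 to 16. With all 4 lists at the same length the ratio was 1.21. The cut gives both receptors the same number of peaks, so it would also remove the excess of a receptor that bound more sites. The ratio therefore cannot tell unequal list lengths from a receptor difference, and list length is no more than a candidate explanation of the imbalance. The cut shortened 3 lists and does not single out human ERα replicate 2. A difference between the receptors stays open. At the same length, pair-specific regions by receptor minus those by replicate number came to −494, the outcome written beforehand as evidence against a receptor difference. That judgement was changed to open after the result was seen, because a larger split by number does not exclude a smaller one by receptor, which still exceeded the crossed pairing (340 against 285).

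Lists with the same replicate number shared regions across receptors that the other number lacked. At the same list length this pairing gave 2.45 times as many pair-specific regions as the higher of the other pairings (834 against 340), which argues against list length as the cause. By Jaccard index at that length the split was not seen for both receptors. Same-number lists of different receptors had a mean of 0.618, and the human ERα replicates had 0.617. The mouse ERα replicates had 0.563, and lists differing in both number and receptor had a mean of 0.570. Replicate 1 lists had wider peaks than replicate 2 lists for both receptors. With each peak replaced by a 500 bp window around its centre the ratio was 2.43 (838 against 345). This argues against width only as it enters the joining of peaks. The windows left unchanged which peaks were called and ranked, so an effect of width at that step stays open. A shared day, cell preparation or sequencing run for each number may be behind the split, and the labels give none of these.

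The MCF7 replicates differed on chromosomes 13 and 19, and a difference in copy number is a candidate explanation, since MCF7 stocks are known to differ in karyotype. Along chromosome 13 the 10 Mb bins differed in their balance of replicate-only peaks (permutation p = 0.00020, 10000 draws, used in place of the Fisher test first written). A break near 30 Mb, as a gained or lost segment would give, was read from the same bins, and the permutation test does not cover its place. The break rests on 1 bin, from 20 to 30 Mb, with 14 peaks in replicate 1 only and 11 in replicate 2 only. However, 9 of 10 bins had more peaks from replicate 2, which had been written as the outcome against a segment, although a segment covering most of the chromosome would give it too. The difference between bins argues against a cause acting evenly along the chromosome only if peaks are taken as independent. MCF7 regions were clumped, with 21.1% having the next within 20 kb against at most 4.51% in random placements, so the p-value may be too small. A copy number difference stays open, since the lists hold no read counts. Base composition stays open as well: leaving out chromosomes 13 and 19, replicate 2 exceeded replicate 1 on GC-poor against GC-rich chromosomes with an odds ratio of 1.11 (95% interval 0.988 to 1.26).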
